A study of Mus musculus with 28 samples.

How the data were processed

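Polyadenylated RNA of epithelial cells scraped by hand from the gastric corpus was sequenced in 28 libraries, 1 per mouse, with a kit that does not mark the strand, so reads from overlapping genes on opposite strands cannot be separated. The deposited data are raw HTSeq read counts for 49492 gene symbols in the 28 libraries, which the authors made with TopHat2 (2.0.14), HTSeq (0.6.1) and the mm10 build, per the labels. The labels also name DESeq2, without a version. The annotation and the strand setting of the counting are not given in the sources used here. Total counts ranged from 10982888 to 30891108 per library, and reads carry no molecular identifiers, so the counting intervals and floors given cover counting error only.

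Libraries were grouped by genotype and age as the labels give them. The column names also carry a library group: the first holds replicates 1 to 3 of 10 weeks and the 25-week libraries except wild-type replicate 3, which is tagged as a replacement, and the second holds replicates 4 and 5 of 10 weeks and all 55-week libraries. The change from 25 to 55 weeks therefore lies across library groups, and that from 10 to 55 weeks does in part. All 28 libraries had the Xist and Ddx3y counts of males (at most 24 and at least 222 counts). Pairs of libraries within a group were compared with sampling noise, as chi-square per degree of freedom. Wild-type replicates 2 and 3 of 10 weeks gave 4.26, and every other pair lay between 15.1 and 168.6. Whether these 2 libraries came from separate mice was not tested.

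Genes were filtered with filterByExpr by group, which left 15812, and scaled with TMM factors. The edgeR (4.0.16) quasi-likelihood F test, two-sided and with robust dispersion, was run on 1 fit of all 28 libraries with a mean for each group. In all 10 contrasts were tested: genotype at each age, 25 and 55 against 10 weeks in each genotype, and the change of the genotype difference between each pair of ages. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the size of the log2 difference divided by the square root of F. Group values are means and SDs of CPM, the counts scaled to a common library total with TMM. Single measures of a library were compared with two-sided exact permutation tests, whose smallest p is 0.00794 for 5 against 5 mice and 0.0286 for 4 against 4.

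Gene lists, 33 in all, were tested with limma (3.58.1) camera at a preset correlation of 0.01, adjusted over the 33 lists within a comparison. Camera with an estimated correlation and fry were run beside it. No list passed camera with an estimated correlation in any genotype comparison. Fry called all 10, 14 and 22 lists that camera called for genotype at 10, 25 and 55 weeks, but fewer for age. In wild-type mice it called 0 of camera's 8 lists from 10 to 25 weeks and 9 of 19 from 10 to 55 weeks. In transgenic mice it called 1 of 9 from 10 to 25 weeks and all 18 from 10 to 55 weeks. The lists, the tests, the other settings first chosen and the rule for naming genes were fixed before the data were examined. The rule names Ppard and Vil1, 23 genes of gastric cell types, growth, PPAR signalling and inflammation, and the 10 largest and 10 smallest log2 differences per genotype comparison among called genes with separated libraries, a mean of at least 1 CPM and an ordinary gene symbol. It also names the 4 members of each list with the lowest adjusted p, and for ages and interactions the 5 genes per direction with the lowest adjusted p. Some genes that the rule names are not reported here. Folds against a group at 0 counts used a floor of 3 counts over the group. Ratios over 1 to 3 counts carry a 95% counting interval.

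Alternatives were DESeq2 size factors, library size alone, no filter, a term for 10-week replicates 4 and 5 or their removal, a replicate block, only the groups compared, DESeq2 (1.42.0) Wald tests, limma-voom with sample weights, a 2-fold threshold and the removal of each library. A term for library group and fits within a library group were added after the data were seen. The tests were checked on simulated data in which 200 genes changed in 1 group, up and down in equal number, and genes varied independently. The real genotype comparisons called 5380 to 9380 genes, so the rates of recovery and false calls may not hold for them. Of genes changed 4-fold, 2-fold and 1.5-fold, edgeR recovered 93.9%, 73.1% and 55.2% at 10 weeks, 84.8%, 59.7% and 38.8% at 25 weeks, and 95.5%, 65.7% and 50.7% at 55 weeks. For changes of the genotype difference it recovered 83.3%, 67.2% and 14.9% from 10 to 25 weeks, 84.8%, 52.2% and 14.9% from 10 to 55 weeks, and 75.8%, 46.3% and 23.9% from 25 to 55 weeks. For ages it recovered 38.8% to 46.3% of genes changed 1.5-fold. False calls by edgeR were 2.4% to 5.61% of calls, except 8.05% for transgenic mice from 10 to 55 weeks. At 10 weeks they were 10.1% for DESeq2 and 5.19% for limma-voom. Positions come from GENCODE M21 on GRCm38, where 15380 of the tested genes have a single place. R 4.3.3, statmod 1.5.0, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.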

Results

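RNA was profiled in epithelial cells scraped from the gastric corpus, the acid-secreting part of the stomach, of mice carrying a villin-PPARD transgene and of their wild-type littermates. PPARD is peroxisome proliferator-activated receptor delta, a lipid-activated nuclear receptor, and the villin promoter is mainly used to drive genes in intestinal epithelium. There were 5 mice per genotype at 10 weeks of age, 4 per genotype at 25 weeks and 5 per genotype at 55 weeks, 28 mice in all with 1 library each. Wild-type replicates 2 and 3 of 10 weeks were far more alike than any other pair within a group. They were counted as separate mice in every test, which was not checked further. The total count per library ranged from 10982888 to 30891108, and 15812 genes passed the count filter. On the 15812 genes, the first principal component held 54.8% of the variance of log2 CPM, the counts scaled to a common library total, and the second 15.9%. The design sets genotypes against each other at each age, and ages against each other within a genotype.

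Ppard and Vil1 were examined first, as a check of the genotype labels. Ppard (ENSMUSG00000002250, chromosome 17, 28232700 to 28301474, GRCm38) averaged 74.1 ± 8.18 CPM (SD, n = 5) in wild-type and 110 ± 9.56 CPM (SD, n = 5) in transgenic mice at 10 weeks. It averaged 73.2 ± 9.05 and 90.6 ± 8.73 CPM (SD, n = 4) at 25 weeks, and 79.4 ± 5.42 and 93.3 ± 7.30 CPM (SD, n = 5) at 55 weeks. The log2 differences were 0.56 ± 0.09 (SE), 0.31 ± 0.10 and 0.23 ± 0.09, and each passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (Ppard adjusted p = 2.548e-05, 0.01834 and 0.03071). At 10 weeks all 5 transgenic libraries lay above all 5 wild-type libraries, while at 25 and 55 weeks the groups overlapped. Two-sided exact permutation tests of log2 CPM gave p = 0.00794, 0.0571 and 0.0159, and 0.0198, 0.0714 and 0.0298 after adjustment over the 15 such tests run. Within the library groups named in the deposited column names, the 10-week log2 difference of Ppard was 0.68 in the first (3 mice per genotype) and 0.44 in the second (2 per genotype). Without wild-type or transgenic replicate 4 the 25-week call of Ppard was lost, and without wild-type replicate 3 or 5, or transgenic replicate 2, 3 or 4, that at 55 weeks. Vil1 (ENSMUSG00000026175, chromosome 1, 74409376 to 74435559), which encodes the brush-border protein villin, rose by a wider margin: from 36.9 ± 9.39 to 142 ± 24.9 CPM (SD, n = 5) at 10 weeks, from 38.3 ± 7.24 to 161 ± 53.3 CPM (SD, n = 4) at 25 weeks, and from 44.4 ± 6.28 to 431 ± 35.2 CPM (SD, n = 5) at 55 weeks. Its transgenic libraries lay above the wild-type libraries at every age. Counts per gene do not separate reads of a transgene from reads of the gene on its own chromosome, so these values do not give the transgene's level.

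**Figure D1:**
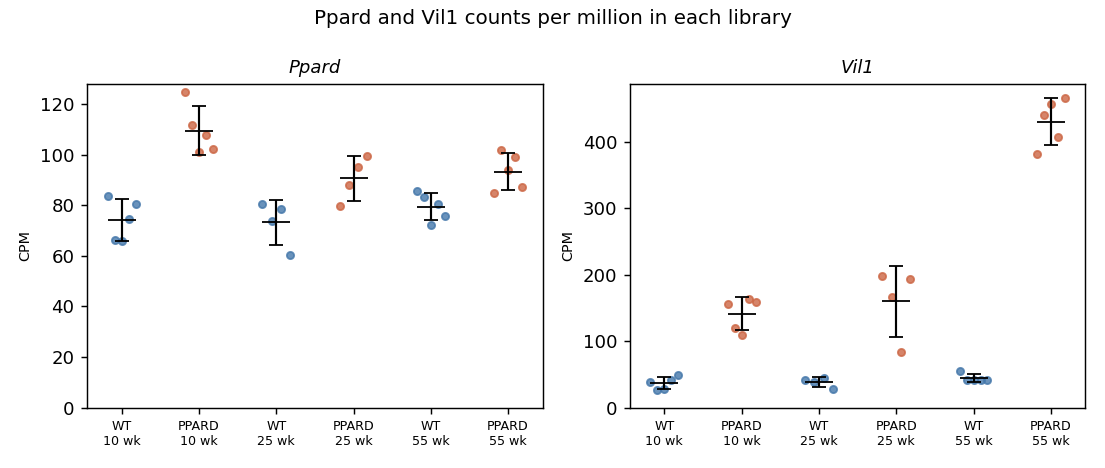
Ppard and Vil1 in each of the 28 libraries, in CPM (left and right panels), by age in weeks and genotype; each point is 1 mouse and the bars give the mean and SD of each group. Vil1 was higher in all transgenic libraries at each age, and Ppard in all of them at 10 weeks only.

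The make-up of the libraries also differed with genotype. Mitochondrially encoded genes took 8.55 ± 2.78% of counts in wild-type and 3.04 ± 1.25% in transgenic mice at 10 weeks (SD, n = 5; exact permutation p = 0.0159). They took 10.5 ± 3.79% and 5.00 ± 0.908% at 25 weeks (SD, n = 4; exact permutation p = 0.0571), and 11.9 ± 5.47% and 3.24 ± 1.30% at 55 weeks (SD, n = 5; exact permutation p = 0.00794). The 10 most abundant genes of a library took 34.5% of wild-type and 27.7% of transgenic counts at 10 weeks, 35.5% and 24.2% at 25 weeks, and 33.3% and 14.6% at 55 weeks (exact permutation p = 0.00794, 0.0286 and 0.00794). Total counts did not differ past the threshold (exact permutation p = 0.7857, 0.8286 and 0.0714). Counts were scaled with TMM factors. With library size as the only scaling, the median log2 difference of all genes moved by 0.16 at 25 weeks and by 0.40 at 55 weeks.

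At 10 weeks, most of the 10 named genes with the largest rises in the transgenic stomach were genes induced by interferons. Slfn4, a Schlafen-family gene (chromosome 11, 83175186 to 83190216), averaged 4.15 ± 1.72 CPM in wild-type and 929 ± 149 CPM in transgenic mice (SD, n = 5), a log2 difference of 7.78 ± 0.34 (SE; edgeR adjusted p = 4.176e-16). Ifi44 averaged 0.520 ± 0.306 and 92.6 ± 11.8 CPM (SD, n = 5; log2 difference 7.35 ± 0.27). The other 8 genes of the named upper 10 were Apol9b, Trim30a, Slfn2, Ifi27l2a, Zbp1 (a sensor of nucleic acids), Nptx2 (a pentraxin), Sp100 and Oas3 (an oligoadenylate synthetase). They were 61.7-fold (Oas3) to 162-fold (Apol9b) higher. In the list of interferon response and antigen presentation genes fixed before the data were examined, 21 of 31 measured members rose and 0 fell, with a median log2 difference of 2.21 (camera adjusted p = 5.03e-21). That list call was lost with an estimated correlation between genes (adjusted p = 0.122). Among its members, the transcription factors Irf7 and Irf9 were 16.05-fold and 3.82-fold higher, the guanylate-binding protein gene Gbp3 was 32.6-fold higher and Oas1a was 8.99-fold higher. Of the immune checkpoint genes 4 of 12 rose and 0 fell (median 0.51, camera adjusted p = 0.0318, adjusted p = 0.592 with an estimated correlation). Within library groups, the interferon list's median was 2.24 in the first and 2.20 in the second. For this and all later lists, the count adjusted over the list alone equals the count over all genes tested unless it is given.

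Markers of leukocytes moved little beside this at 10 weeks. Of the myeloid markers 2 of 22 rose (Mpeg1, log2 difference 1.88, and Cd68, 0.86) and 0 fell, with a median of 0.09. Of the T and natural killer cell markers 0 of 10 passed the test. These 10 averaged only 0.0359 (Gzmb) to 0.988 CPM (Cd4) in wild-type mice, so a rise could be missed. Of the B and plasma cell markers, Cd22 rose and Derl3 fell among 12. Fibroblast markers had 2 of 16 higher, and endothelial markers 2 of 13 higher, including the angiopoietin receptor gene Tek at a log2 difference of 3.92. Smooth muscle markers had 0 of 13 past the test.

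The proliferation and epidermal growth factor family lists rose at 10 weeks, and the parietal cell, endocrine cell and respiratory chain lists fell. Of the proliferation genes 17 of 30 rose and 0 fell, by a median of 0.44 (camera adjusted p = 0.000104, adjusted p = 0.592 with an estimated correlation). Mki67, a marker of cycling cells, went from 86.3 ± 19.7 to 123 ± 8.45 CPM (SD, n = 5; edgeR adjusted p = 8.198e-03), and the replication helicase gene Mcm6 was 1.65-fold higher. Of the epidermal growth factor family ligands and receptors 8 of 11 rose, by a median of 0.87 (camera adjusted p = 0.00154, adjusted p = 0.592 with an estimated correlation), including Egfr (2.39-fold), Areg (2.23-fold) and Hbegf (1.82-fold). Of the parietal cell markers 14 of 21 fell and 0 rose (median −0.57, camera adjusted p = 9.21e-05, adjusted p = 0.592 with an estimated correlation). The proton pump subunit genes were among them. Atp4a fell from 10715 ± 649 to 6589 ± 582 CPM and Atp4b from 4534 ± 522 to 2717 ± 225 CPM (SD, n = 5; edgeR adjusted p = 0.02568 and 0.03720), each with all 5 transgenic libraries below all 5 wild-type ones. Of the endocrine cell markers 9 of 21 fell and 0 rose (median −0.72, camera adjusted p = 0.00102, adjusted p = 0.592 with an estimated correlation), including Sst, which encodes somatostatin, at 1.85-fold lower. Of the mitochondrial respiratory chain genes 24 of 30 fell (25 adjusted over the list alone) and 0 rose, by a median of −0.40 (camera adjusted p = 6.68e-11, adjusted p = 0.592 with an estimated correlation), beside the lower share of mitochondrially encoded counts given above.

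Other mucosal lists were mixed at 10 weeks. Of the chief cell markers 6 of 14 fell and 1 rose, without a list call (median −0.59, camera adjusted p = 0.169). Clps (colipase) fell from 20026 ± 5789 to 8497 ± 1369 CPM and Pgc (pepsinogen C) from 97247 ± 22004 to 50955 ± 5668 CPM, while Gif (gastric intrinsic factor) did not pass the test at 2393 ± 711 and 1667 ± 238 CPM (SD, n = 5; edgeR adjusted p = 0.283). Of the pit cell markers 3 of 16 rose (2 adjusted over the list alone) and 1 fell. The surface mucin gene Muc5ac went from 16547 ± 2646 to 25319 ± 2894 CPM (SD, n = 5; edgeR adjusted p = 0.04932), and Muc1 was 2.14-fold higher. Of the mucous neck and spasmolytic polypeptide-expressing metaplasia (SPEM) markers 6 of 18 rose and 0 fell, by a median of 0.51 (camera adjusted p = 0.0318, adjusted p = 0.592 with an estimated correlation), with Aqp5 2.07-fold and Clu 1.74-fold higher. Muc6 and Cd44 did not pass the test in that list, at log2 differences of 0.68 and 0.47. The call of the mucous neck and SPEM list was lost within the first library group and with library size as the only scaling. Matrix remodelling and invasion genes had 9 of 24 higher and 1 lower (median 0.48, camera adjusted p = 0.0160, adjusted p = 0.708 with an estimated correlation), a call that was lost within the second library group. Of the epithelial cytokine, chemokine and acute-phase genes 5 of 24 rose and 1 fell (median 0.18, camera adjusted p = 0.0399, adjusted p = 0.708 with an estimated correlation), a call that was lost with library size as the only scaling. The 5 included the hydrogen peroxide-producing oxidase Duox2 (9.12-fold), its maturation factor Duoxa2 (12.1-fold), the alarmin gene Il33 (4.36-fold) and the chemokine gene Ccl20, at 4.17 ± 1.51 and 17.7 ± 2.23 CPM (SD, n = 5; edgeR adjusted p = 1.484e-06). Of the PPAR target and fatty acid oxidation genes 6 of 30 rose (7 adjusted over the list alone) and 5 fell. Vnn1, a pantetheinase gene, was 12.8-fold higher and the fatty acid-binding protein gene Fabp3 was 2.58-fold lower, while Angptl4 and Pdk4 did not pass the test (log2 differences 0.65 and −0.61).

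The genes with the largest falls at 10 weeks changed far less than those that rose. Mug1, a protease inhibitor gene, fell from 14.8 ± 3.05 to 2.25 ± 0.727 CPM (SD, n = 5), or 6.49-fold, and mt-Co2 from 6.10 ± 6.32 to 1.03 ± 0.334 CPM (5.80-fold), of which 1 wild-type library reached 17.3 CPM. The rest of the named lower 10 were Fzd10, Epdr1, Epb41l3, Upk3a, mt-Rnr2, Cyp4a32, Scnn1b and Smim5, between 3.84-fold (Smim5) and 6.14-fold (Fzd10) lower. Mitochondrial genes have nuclear copies of near-identical sequence, and Schlafen genes are a close family, so their split of reads is uncertain. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05, 5380 of 15812 genes were called at 10 weeks, 2823 higher and 2557 lower, and 1066 of them differed by 2-fold or more. With library size as the only scaling, the calls were 61.7% higher, against 52.5% with TMM. The groups did not overlap at all for 25.6% of genes, where chance gives 0.79%. Within library groups there were 2803 calls in the first and 1891 in the second, which hold fewer mice.

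At 25 weeks interferon-induced genes again had the largest rises among the named genes. Slfn4 averaged 3.56 ± 0.958 CPM in wild-type and 1232 ± 468 CPM in transgenic mice (SD, n = 4; log2 difference 8.42 ± 0.39; edgeR adjusted p = 2.910e-15), and Ifi44 0.464 ± 0.320 and 131 ± 39.8 CPM. Next came Apol9b, Slfn2, Trim30a, Oas3, Ifit1, Zbp1, Ido1 (a tryptophan-degrading enzyme) and Ifit1bl1, between 80.2-fold (Ifit1bl1) and 182-fold (Apol9b) higher. Of the interferon response and antigen presentation genes 22 of 31 rose and 0 fell, by a median of 2.52 (camera adjusted p = 3.43e-17, adjusted p = 0.213 with an estimated correlation). The immune checkpoint genes had 4 of 12 higher (median 0.70, camera adjusted p = 0.0256, adjusted p = 0.434 with an estimated correlation), a call that was lost with library size as the only scaling, and among them were Vtcn1 and Cd274, which encodes the ligand PD-L1 (log2 differences 2.67 and 1.56). The lowest named genes were Epb41l3, Mug1, Hmcn2, Abca8a, Cyp2b10, Adamtsl2, Rab37, Crybb3, Col20a1 and Kazald1, from 10.8-fold (Epb41l3) to 5.38-fold (Kazald1) lower.

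Proliferation genes rose nearly throughout at 25 weeks: 28 of 30 were higher and 0 lower, by a median of 0.86 (camera adjusted p = 1.16e-13, adjusted p = 0.279 with an estimated correlation). Mki67 went from 86.9 ± 26.3 to 157 ± 17.0 CPM (SD, n = 4), and Top2a, Tpx2 and Kif11, which act in mitosis, rose by log2 differences of 1.11, 1.14 and 1.16. Of the mucous neck and SPEM markers 10 of 18 rose and 0 fell. Their median was 0.87, or 0.78 with a gene at 0 counts set to its bound (camera adjusted p = 0.00184, adjusted p = 0.296 with an estimated correlation). The adhesion receptor gene Cd44 went from 6.46 ± 1.07 to 19.7 ± 10.99 CPM (SD, n = 4; edgeR adjusted p = 3.679e-05). Of the epidermal growth factor family genes 7 of 11 rose (8 adjusted over the list alone) and 1 fell (median 0.89, camera adjusted p = 0.00364, adjusted p = 0.296 with an estimated correlation). Of the epithelial cytokine and chemokine genes 10 of 24 rose and 0 fell, with a median of 1.31, or 1.09 with genes at 0 counts set to their bounds (camera adjusted p = 0.00817, adjusted p = 0.502 with an estimated correlation), and their call was also lost with library size as the only scaling. Ccl20 reached 33.4 ± 17.3 CPM against 4.24 ± 0.447 in wild-type mice (SD, n = 4). Matrix remodelling genes had 15 of 24 higher and 1 lower (median 0.72, camera adjusted p = 0.00941, adjusted p = 0.668 with an estimated correlation), with the metalloproteinase gene Mmp10 at a log2 difference of 4.95. Claudins and tight junction genes had 10 of 15 higher and 1 lower (median 0.51, camera adjusted p = 0.0134, adjusted p = 0.421 with an estimated correlation), with Cldn4, Cldn23 and Cldn2 at 3.70, 3.11 and 3.04.

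Markers of acid-, enzyme- and hormone-secreting cells fell at 25 weeks. Of the parietal cell markers 15 of 21 fell (16 adjusted over the list alone) and 0 rose (median −0.70, camera adjusted p = 1.33e-05, adjusted p = 0.296 with an estimated correlation), with Atp4a at 8689 ± 2118 and 4223 ± 1384 CPM (SD, n = 4) and Atp4b at 4228 ± 811 and 2088 ± 735 CPM. Of the chief cell markers 8 of 14 fell (9 adjusted over the list alone) and 1 rose, the rennin gene Cym (median −1.15, camera adjusted p = 0.0134, adjusted p = 0.434 with an estimated correlation). Pgc fell from 85541 ± 21955 to 28925 ± 15296 CPM and Clps from 17360 ± 5388 to 4709 ± 3030 CPM (SD, n = 4). Amy2b was at 0 counts in the transgenic mice and at least 33.5-fold lower, over the group. Of the endocrine markers 11 of 21 fell (12 adjusted over the list alone) and 0 rose (median −0.93, camera adjusted p = 2.85e-05, adjusted p = 0.296 with an estimated correlation). Of the respiratory chain genes 26 of 30 fell (27 adjusted over the list alone, median −0.52, camera adjusted p = 3.05e-13, adjusted p = 0.296 with an estimated correlation). All 4 erythroid markers fell (median −1.74, camera adjusted p = 0.0218, adjusted p = 0.434 with an estimated correlation). Pit cell markers were mixed, 4 of 16 higher and 3 lower: Gkn1 (gastrokine 1) fell from 59221 ± 5984 to 33275 ± 4053 CPM (SD, n = 4), while Muc5ac did not pass the test, at 15323 ± 2210 and 19792 ± 5489 CPM. In all, 6262 genes were called at 25 weeks by the same edgeR test, 3318 higher and 2944 lower, and 1789 by 2-fold or more. With library size as the only scaling, the calls were 74.5% higher, against 52.99% with TMM. Groups did not overlap for 27.3% of genes, where chance gives 2.86%. The wild-type library of replicate 3 carries its own library tag. The first library group alone gave 4782 calls.

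At 55 weeks the named lower 10 were Chia1, Pla2g1b, Try10 (a trypsinogen gene), Amy2b (an amylase gene), Necab1, Clps, Gper1, Gif, Sostdc1 and Pgc. Chia1 (acidic chitinase) fell from 8587 ± 3876 to 18.8 ± 11.4 CPM, Pla2g1b (a digestive phospholipase) from 10958 ± 4642 to 31.3 ± 12.6 CPM, and Clps from 12035 ± 4945 to 63.4 ± 25.1 CPM (SD, n = 5). These are log2 differences of −8.83 ± 0.65 for Chia1, −8.45 ± 0.47 for Pla2g1b and −7.57 ± 0.48 for Clps (SE; edgeR adjusted p = 1.724e-11, 2.756e-14 and 4.941e-13). Pgc (chromosome 17, 47726842 to 47734482) fell 74.7-fold, from 51078 ± 20660 to 683 ± 404 CPM, and Gif (chromosome 19, 11747554 to 11763447) 94.5-fold, from 1665 ± 452 to 17.6 ± 11.8 CPM (SD, n = 5). Of the chief cell markers 12 of 14 fell and 0 rose, by a median of −3.54 (camera adjusted p = 1.13e-06, adjusted p = 0.0809 with an estimated correlation). Of the parietal cell markers 17 of 21 fell and 2 rose, by a median of −2.33 (camera adjusted p = 3.57e-09, adjusted p = 0.0809 with an estimated correlation). Atp4a fell from 4874 ± 1196 to 185 ± 89.4 CPM and Atp4b from 2457 ± 627 to 85.7 ± 50.2 CPM (SD, n = 5). The histamine receptor gene Hrh2 and the potassium channel gene Kcnj16 fell by log2 differences of −4.46 and −4.67. The endocrine markers had 15 of 21 lower and 1 higher (median −2.76, camera adjusted p = 2.69e-07, adjusted p = 0.136 with an estimated correlation), with Sst at −5.62. Pit cell markers had 12 of 16 lower and 2 higher (median −1.43, camera adjusted p = 2.49e-05, adjusted p = 0.262 with an estimated correlation). Gkn1 fell from 56030 ± 11132 to 11162 ± 4139 CPM and Muc5ac from 15836 ± 3451 to 4197 ± 2043 CPM (SD, n = 5).

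**Figure D2:**
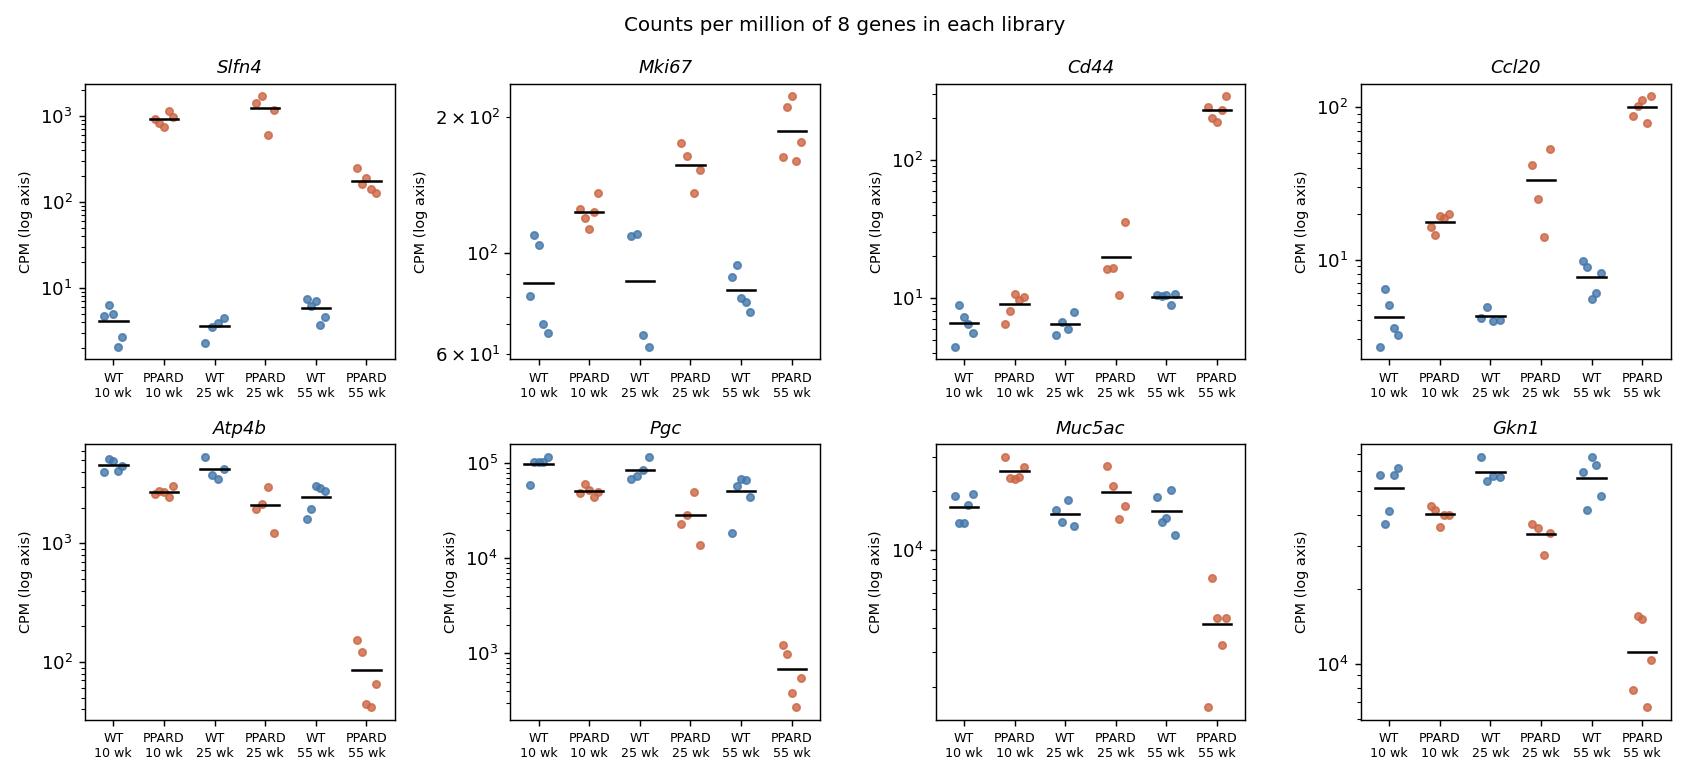
CPM on a log axis for Slfn4, Mki67, Cd44, Ccl20, Atp4b, Pgc, Muc5ac and Gkn1 in the 28 libraries, by age and genotype; each point is 1 mouse and each bar marks the group mean. Slfn4 was higher in every transgenic library at each age, while Pgc and Atp4b fell furthest at 55 weeks, to 683 and 85.7 CPM on average.

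Many mucous neck, SPEM and intestinal genes were higher at 55 weeks. Of the mucous neck and SPEM markers 15 of 18 rose and 2 fell, by a median of 2.50 (camera adjusted p = 3.74e-07, adjusted p = 0.0809 with an estimated correlation). Cd44 went from 10.2 ± 0.759 to 230 ± 39.3 CPM (SD, n = 5; edgeR adjusted p = 1.143e-14), and Olfm4, Wfdc18 and Dmbt1 rose by log2 differences of 5.88, 8.04 and 3.34. The neck mucin gene Muc6 went the other way, from 692 ± 168 to 221 ± 127 CPM (SD, n = 5), and Aqp5 also fell, by a log2 difference of −1.27. Tff2, the spasmolytic polypeptide itself, did not pass the test (log2 difference −0.27; edgeR adjusted p = 0.236). Of the intestinal epithelium markers 14 of 21 rose and 5 fell, by a median of 2.74 (camera adjusted p = 0.0455, adjusted p = 0.262 with an estimated correlation). The list's call was also lost with library size as the only scaling. The membrane mucins Muc3, from 0.265 ± 0.217 to 104 ± 33.3 CPM (SD, n = 5), and Muc13, with a log2 difference of 6.18, were among those that rose, as was the goblet cell peptide gene Tff3 (2.74). The apolipoprotein genes Apoa1 and Apoa4 fell (−4.84 and −5.30), and Cdx2 did not pass the count filter. By fitted log2 difference, the highest named genes were Slc13a2, Khdc1a, Prap1, Adgrg7, Nox1, Khdc1c, Muc3, Cxcl5, Mep1b and Vnn3. The places of genes at 0 counts in wild-type mice rest on the fit, and their bounds do not fix that order. Slc13a2, Khdc1a, Khdc1c and Vnn3 had 0 counts in the 5 wild-type libraries and were at least 195-fold, 171-fold, 80.5-fold and 65.6-fold higher, with 3 counts over the group as the floor. Nox1, a superoxide-producing oxidase gene, went from 0.0585 ± 0.0741 to 51.7 ± 37.4 CPM, and Adgrg7 from 0.212 ± 0.0528 to 185 ± 98.6 CPM (SD, n = 5).

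Immune and inflammatory genes were raised broadly at 55 weeks. Of the epithelial cytokine, chemokine and acute-phase genes 21 of 24 rose and 1 fell (2 adjusted over the list alone), by a median of 3.83 (camera adjusted p = 2.37e-06, adjusted p = 0.160 with an estimated correlation). Ccl20 went from 7.66 ± 1.83 to 99.9 ± 16.4 CPM and the neutrophil chemokine gene Cxcl5 from 0.0938 ± 0.0949 to 42.7 ± 25.1 CPM (SD, n = 5). Tnf, Il1a and Il1b rose by log2 differences of 5.84, 6.12 and 3.63. All 31 interferon response and antigen presentation genes rose, by a median of 2.82 (camera adjusted p = 4.51e-13, adjusted p = 0.126 with an estimated correlation), and all 12 immune checkpoint genes, by a median of 2.16 (camera adjusted p = 0.000164, adjusted p = 0.136 with an estimated correlation). Markers of leukocytes rose beside these lists. All 10 T and natural killer cell markers rose (median 2.29, camera adjusted p = 0.00246, adjusted p = 0.269 with an estimated correlation), 11 of 12 B and plasma cell markers rose and 1 fell (median 2.62, camera adjusted p = 0.00171, adjusted p = 0.269 with an estimated correlation), and 17 of 22 myeloid markers rose and 0 fell (median 1.21, camera adjusted p = 0.000753, adjusted p = 0.369 with an estimated correlation). The neutrophil calcium-binding gene S100a8 had 1 count in the wild-type libraries, and its ratio was 225, with a counting interval (95%) of 40.2 to 8924.

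All 30 proliferation genes rose at 55 weeks, by a median of 1.66 (camera adjusted p = 7.65e-17, adjusted p = 0.0809 with an estimated correlation), with Mki67 at 83.0 ± 8.13 and 186 ± 28.3 CPM (SD, n = 5). Matrix remodelling genes had 17 of 24 higher and 2 lower (median 1.004, camera adjusted p = 0.00246, adjusted p = 0.382 with an estimated correlation), claudins and tight junction genes 11 of 15 higher and 1 lower (2 adjusted over the list alone, median 0.56, camera adjusted p = 0.00777, adjusted p = 0.262 with an estimated correlation). Epidermal growth factor family genes had 8 of 11 higher, while Egf itself fell by a log2 difference of −2.83 (median 0.97, camera adjusted p = 0.0176, adjusted p = 0.269 with an estimated correlation). Lipid and sterol synthesis genes had 12 of 19 higher and 0 lower (median 0.52, camera adjusted p = 0.00246, adjusted p = 0.324 with an estimated correlation), with the desaturases Scd2 and Scd1 at 2.29 and 1.90. PPAR target and fatty acid oxidation genes had 4 of 30 higher and 10 lower (median −0.29, camera adjusted p = 0.0172, adjusted p = 0.512 with an estimated correlation), a call that was lost without a filter. Vnn1 and the lipid-droplet gene Plin2 rose (5.77 and 1.97), Fabp3 and the fatty acid transporter gene Cd36 fell (−5.44 and −4.27), and Pdk4 did not pass the test (−0.32). Respiratory chain genes had 26 of 30 lower (median −0.54, camera adjusted p = 1.15e-07, adjusted p = 0.269 with an estimated correlation). Lgr5, a Wnt target and stem cell marker, fell by a log2 difference of −3.85, while Myc and Ccnd1 of the Wnt target list rose (1.999 and 1.48). That list had 8 of 14 higher (9 adjusted over the list alone) and 2 lower, without a list call (camera adjusted p = 0.0725).

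The same edgeR test called 9380 of 15812 genes at 55 weeks, 5009 higher and 4371 lower, and 4057 by 2-fold or more. With library size as the only scaling, the calls were 78.9% higher, against 53.4% with TMM. Groups did not overlap for 43.3% of genes, where chance gives 0.79%. All 10 libraries of this age are in the second library group, so no comparison within another group could be made. Genes of the trypsinogen and amylase families (Try10, Try5, Amy2b) and Khdc1a with Khdc1c have close paralogs, and their shares of reads are uncertain.

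Across the 3 ages, many of the same genes were called in the same direction. Over 15812 genes, the log2 differences at 10 and 25 weeks correlated with r = 0.77, those at 10 and 55 weeks with r = 0.47, and those at 25 and 55 weeks with r = 0.60. These are correlations across genes, which are not independent replicates, and the ages share no mice. At 10 and 25 weeks, 2049 genes were higher at both ages and 1657 lower at both, where lists drawn independently would share 592 and 476, and 4 genes were called in opposite directions. At 10 and 55 weeks the shared calls were 1606 and 1611 (894 and 707 for independent lists), with 524 opposite. At 25 and 55 weeks they were 2115 and 2003 (1051 and 814 for independent lists), with 325 opposite. At all 3 ages 1350 genes were higher and 1253 lower, including Slfn4, Ifi44, Mki67 and Ccl20 among the higher and Atp4a, Atp4b, Mug1 and Clps among the lower. Without a filter on low counts the 3 correlations were 0.35, 0.28 and 0.35.

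**Figure D3:**
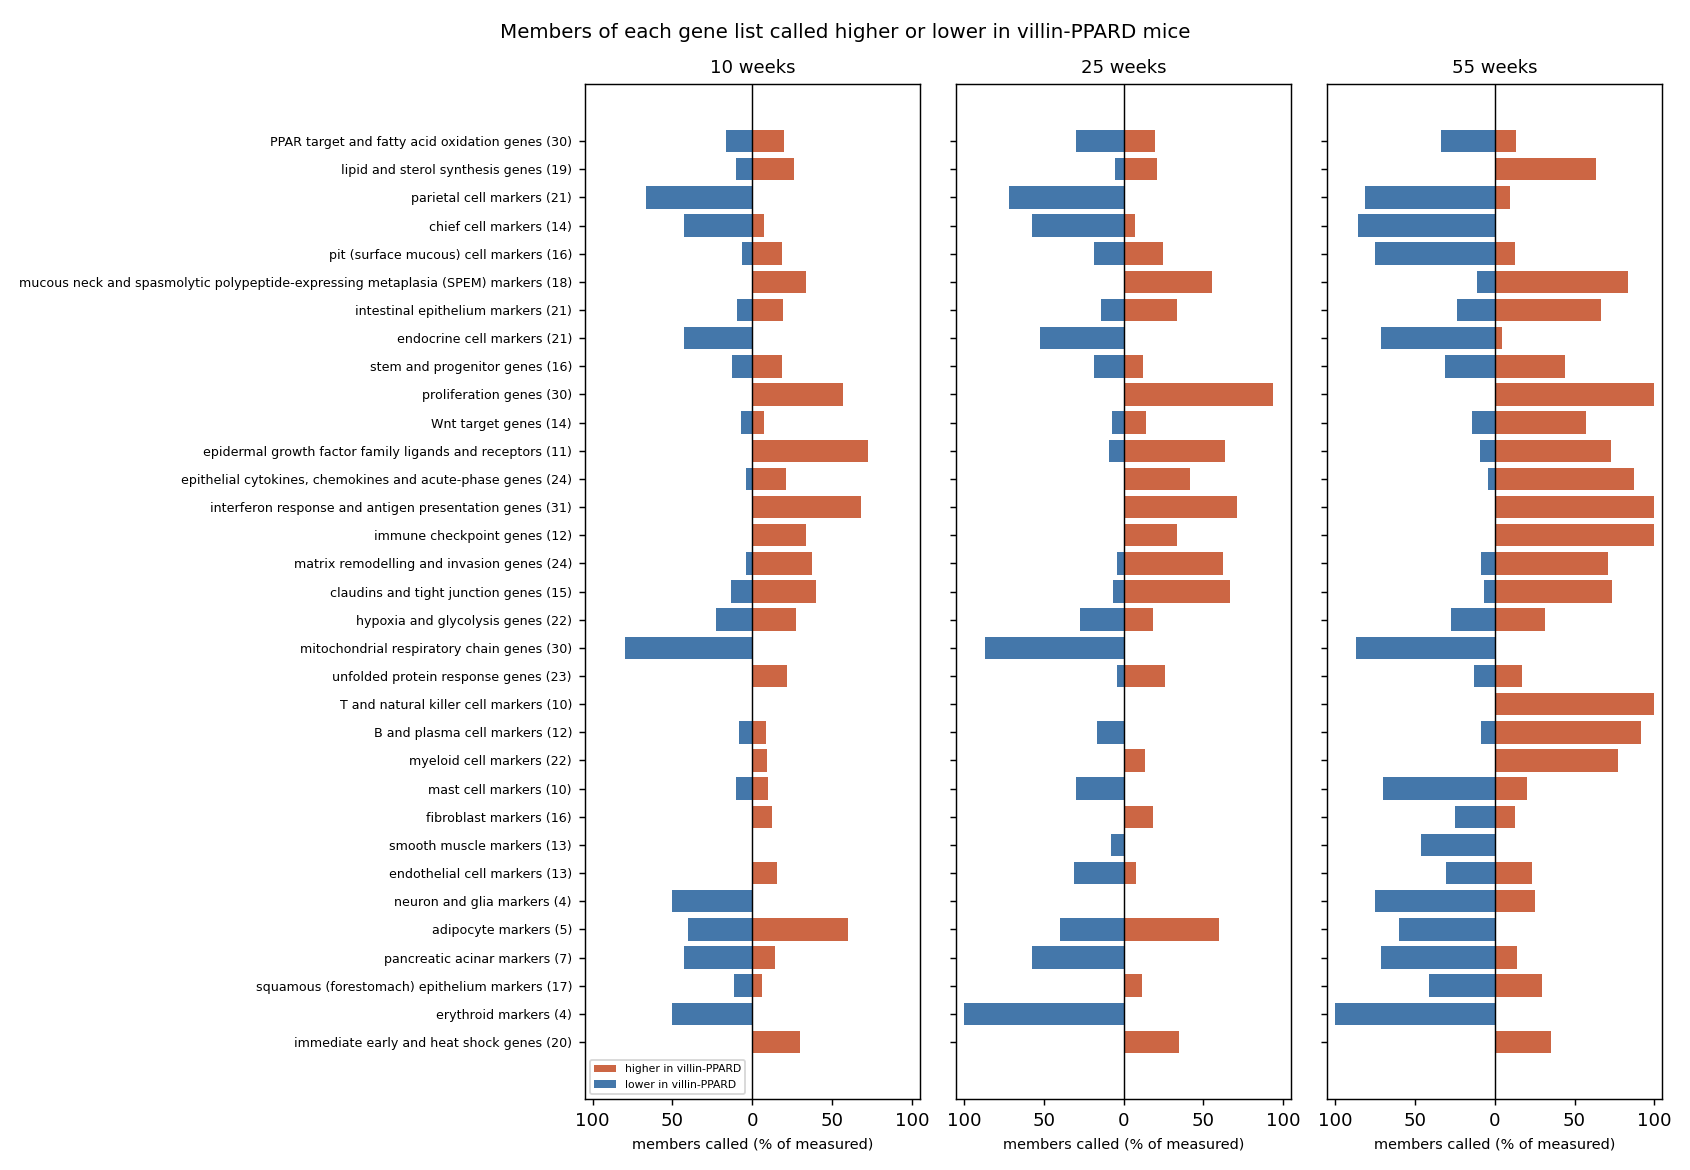
Share of each list's measured members (percent, horizontal axis; number measured in brackets) called higher (right of 0) or lower (left of 0) in villin-PPARD mice at 10, 25 and 55 weeks (panels from left to right). All 30 proliferation genes and all 31 interferon response and antigen presentation genes were higher at 55 weeks, against 17 and 21 at 10 weeks.

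The difference between genotypes was next tested for change with age, as a term of the same model. Between 10 and 25 weeks, 1 gene changed its genotype difference, the methyltransferase gene Setd4, by a log2 value of −0.998 ± 0.16 (SE; edgeR adjusted p = 0.01093), among 1810 genes with an unadjusted p under 0.05. DESeq2 and limma-voom called 47 and 130 genes. The count was 0 without transgenic replicate 1 of 25 weeks 32 without transgenic replicate 3 of that age, 11 without wild-type replicate 5 of 10 weeks, 3 without transgenic replicate 3 of 10 weeks, and 2 without wild-type replicate 4 of 10 weeks or wild-type replicate 1 or 2 of 25 weeks. Between 10 and 55 weeks 5748 genes did, 2905 upward and 2843 downward, and between 25 and 55 weeks 4570 did, 2255 upward and 2315 downward. C4bp, which encodes a complement regulator, showed no genotype difference past the threshold at 10 weeks and rose at 55 weeks, with a change of 5.21 ± 0.22 (SE; edgeR adjusted p = 2.781e-16). The Wnt receptor gene Fzd1, the DNA repair gene Brca1 and Rbbp7 also moved upward from 10 to 55 weeks, and Hrh2, the growth factor-binding gene Fgfbp1, Gsdma2 (a gasdermin), Vars2 and Pstpip1 moved downward. Fzd1 was lower in transgenic mice at 10 weeks (log2 difference −0.64) and higher at 55 weeks (2.04). The 25 and 55 week libraries lie in different library groups. Only the second library group holds mice of both genotypes at 10 and 55 weeks, and within it 3636 genes were called for that change.

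Within wild-type mice, few genes differed between 10 and 25 weeks. Tpsab1 and Tpsb2, which encode mast cell tryptases, rose from 10 to 25 weeks by log2 differences of 1.76 ± 0.27 and 1.495 ± 0.26 (SE; edgeR adjusted p = 0.007802 and 0.03161), and were the 2 genes called. Both calls were lost with library group as a term, which left 0 calls by edgeR (672 genes had an unadjusted p under 0.05), and 0 genes were called without any 1 of wild-type replicates 1, 2 and 3 of 10 weeks or 1 and 4 of 25 weeks, and 1 without wild-type replicate 5 of 10 weeks. From 10 to 55 weeks 2007 genes were called, 1017 higher and 990 lower, among them Tpsb2, Tpsab1, Mcpt4 (a mast cell protease gene) and Jchain, the joining chain gene of secreted immunoglobulin, at log2 differences of 2.57, 2.61, 2.54 and 3.61. Mast cell markers had 8 of 10 higher (9 adjusted over the list alone) and 1 lower (median 1.75, camera adjusted p = 1.93e-08, adjusted p = 0.120 with an estimated correlation), and B and plasma cell markers 7 of 12 higher and 1 lower (median 2.36, camera adjusted p = 3.51e-07, adjusted p = 0.167 with an estimated correlation). Parietal cell markers had 16 of 21 lower (18 adjusted over the list alone) and 0 higher (1 adjusted over the list alone, median −0.75, camera adjusted p = 9.42e-13, adjusted p = 0.0877 with an estimated correlation). Respiratory chain genes had 23 of 30 lower (27 adjusted over the list alone, median −0.40, camera adjusted p = 6.60e-16, adjusted p = 0.190 with an estimated correlation). Plekhn1 also rose, and Ppm1l, Gpam, Epb41l3, Gpr155 and Enpp4 fell. With library group as a term 626 genes were called, and within the second library group alone, with 2 mice at 10 weeks, 243. Without wild-type replicate 2 of 55 weeks the count was 1203, and without wild-type replicate 1 of 10 weeks 1299.

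Within villin-PPARD mice the change with age was tested in the same way. From 10 to 25 weeks 445 genes were called, 315 higher and 130 lower. With library group as a term the count was 208, and DESeq2 and limma-voom gave 1132 and 2972. Proliferation genes had 8 of 30 higher (15 adjusted over the list alone, median 0.37, camera adjusted p = 6.01e-11, adjusted p = 0.513 with an estimated correlation), and Nap1l1, Slfn9, Fam111a, Aim2 and the surfactant protein gene Sftpd had the lowest adjusted p among genes that rose, and Setd4, Epb41l3, Itpka, B4galnt3 and Dgat1 among genes that fell. This count moved with single mice. It was 87, 64, 750 and 263 without transgenic replicates 1, 2, 3 and 5 of 10 weeks, and 78, 205, 1862 and 83 without transgenic replicates 1, 2, 3 and 4 of 25 weeks. From 10 to 55 weeks 8180 genes were called, 4302 higher and 3878 lower. C4bp, Noxo1 (an activator of Nox1), Shf, Rbbp7 and Tns4 rose by log2 differences of 4.56, 4.28, 5.52, 2.22 and 4.43. Dcbld2, Hrh2, the amino acid transporter gene Slc7a8, the potassium channel gene Kcnj15 and Vars2 fell, by −2.62, −4.55, −4.23, −2.86 and −2.46. All 30 proliferation genes rose from 10 to 55 weeks (median 0.98, camera adjusted p = 3.91e-13, adjusted p = 0.146 with an estimated correlation). The interferon list did not move as a whole, with 13 of 31 higher (14 adjusted over the list alone) and 10 lower (camera adjusted p = 0.690). Slfn4 fell between these ages to 174 ± 47.7 CPM at 55 weeks (SD, n = 5), where wild-type mice had 5.82 ± 1.62 CPM.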

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

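The tests of leukocyte markers, of library group at 10 weeks, of the make-up of the wild-type scrapes and of the pancreatic-type genes were chosen after the results were seen.

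In the genotype comparisons chance can be excluded for the numbers of genes called. At 10 weeks 5380 genes were called and at most 1597 in the other splits drawn (1 of 100 splits as large, the real one), at 25 weeks 6262 and at most 4213 (1 of 35), and at 55 weeks 9380 and at most 5407 (1 of 100). For change with age it can be excluded in wild-type mice from 10 to 55 weeks (2007 against at most 309, 1 of 100) and in transgenic mice from 10 to 55 weeks (8180 against at most 3651, 1 of 100). From 10 to 25 weeks in transgenic mice the splits do not settle it. The 445 genes called were reached by 2 of 100 splits, the real one included. A split that grouped transgenic replicate 3 of 25 weeks with the 10-week mice gave 478, and removal of single mice gave 64 to 1862, the latter without that library. It stood apart from the other transgenic libraries of 25 weeks. Its first principal component was −17.2 against 6.17 to 32.4, and its Vil1 83.4 CPM against 166 to 199 CPM. Its limma-voom sample weight, 0.289, was the lowest of the 28 libraries. The 25-week split with 4213 calls placed it with wild-type replicates 1, 3 and 4. Why it differed was not tested. From 10 to 25 weeks in wild-type mice it cannot be excluded: 8 of 100 splits gave at least the 2 genes called, and the split that put 10-week replicates 1 to 3 with 25-week replicates 1 and 2 gave 156. A count so far above the real one points to a structure of the samples. The splits with 156 and 83 calls, the largest counts, both set 10-week replicates 1 to 3 against replicates 4 and 5, as library group does. Each of the others with at least 2 calls also kept replicates 4 and 5 together. Those with 3, 5, 14 and 17 calls, however, put replicate 1 or 3 of the first library group with them, so the splits do not identify the structure. Library group stays open for this comparison. The correlations between ages lay beyond those of all other splits drawn: 0.77 against 0.57 (1 of 35), 0.468 against 0.467 (1 of 100) and 0.60 against 0.56 (1 of 35). Splits of the 2 ages were paired in the order drawn, which covers few of the possible pairs. The lead at 10 and 55 weeks is too small to tell whether another draw would exceed it. For the number of lists called by camera, chance cannot be excluded at 10 weeks (10 lists, 51 of 100 splits as many, at most 19) or 25 weeks (14 lists, 7 of 35, at most 17). At 55 weeks the splits do not settle it (22 lists, 2 of 100, the real one included). Another split also called 22 lists, and the median of the other splits was 15. By their own medians, 12, 9 and 22 of the 33 lists lay beyond all other splits at the 3 ages. Of the lists called by camera, those not beyond all other splits were at 10 weeks the mucous neck and SPEM (2 of 100 splits as large), cytokine (48), immune checkpoint (11) and matrix remodelling lists (9). At 25 weeks they were the mucous neck and SPEM (2 of 35), checkpoint (2), matrix remodelling (3), claudin (2), respiratory chain (2) and immediate early lists (3), and at 55 weeks the PPAR target (7 of 100), claudin (2) and adipocyte lists (5).

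The genotype difference itself differed between ages. From 10 to 25 weeks it changed for 1 gene, Setd4, by −0.998, and chance cannot be excluded for that number (6 of 100 splits as large, at most 1339). The split with 1339 relabelled 2 transgenic and 4 wild-type libraries, and its count too points to a structure of the samples that was not identified. Without transgenic replicate 3 of 25 weeks, the library set apart above, the count for the real ages was 32. From 10 to 55 weeks it changed for 5748 genes (1 of 100 splits as large, at most 5380), and from 25 to 55 weeks for 4570 (1 of 100, at most 4549). These splits exchanged ages within each genotype, so they stand for no age change in either genotype. They cannot decide whether chance accounts for a difference between the age changes of the genotypes. The highest other splits are not values without an age change in transgenic mice: the split with 4549 relabelled 0 transgenic and 4 wild-type libraries, and that with 5380 relabelled all 10 transgenic libraries, which mirrors their ages, and 6 wild-type ones. Among the genes with the lowest adjusted p from 10 to 55 weeks were C4bp (5.21), Rbbp7 (2.29), Fzd1 (2.68) and Brca1 (2.76) upward, and Gsdma2 (−2.77), Vars2 (−2.39), Pstpip1 (−3.71), Hrh2 (−3.89) and Fgfbp1 (−3.17) downward. From 25 to 55 weeks they were C4bp (4.75), Fzd1 (2.57), Shisa2 (3.17), Tm7sf2 (2.17) and Shf (5.75) upward, and Gsdmc4 (−2.59), Gsdma2 (−2.34), Fgfbp1 (−2.98), Hrh2 (−3.48) and Dcbld2 (−1.87) downward.

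Single libraries lay far from the rest of their group in 8 of 162 groups of values, where chance gives about 8.1. Vil1 was 55.6 CPM in wild-type replicate 1 of 55 weeks, and the next library had 42.1. At 10 weeks mt-Co2 was 17.3 CPM in wild-type replicate 2 (next 4.24), Pgc 59285 CPM in wild-type replicate 1 (next 102033) and Muc6 1660 CPM in transgenic replicate 5 (next 1110). Cd44 was 8.92 CPM in wild-type replicate 4 of 55 weeks (next 10.3). At 25 weeks Adgrg7 was 2.68 CPM (next 0.335) and Muc3 4.99 CPM (next 0.669) in transgenic replicate 4, and Muc3 was 0.785 CPM in wild-type replicate 3 (next 0.0539).

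The interferon-induced genes of 10 weeks were weighed first. More leukocytes would raise leukocyte markers by about as much, but the highest transgenic library exceeded the lowest wild-type library by 0.805 in the mean log2 CPM of 44 markers, under the list's median of 2.21. That bound holds for the pooled markers. Some, such as Gzmb and Cd79a (0.036 and 0.074 CPM in wild-type mice), had too few counts to show a rise in full. Mpeg1, Cd22 and Cd68 rose (1.88, 1.75 and 0.86) and Derl3 fell (−1.21). A change of single leukocyte types or of their activity was not tested. Neither library group nor GC content and gene length account for it: the lower median within a library group was 2.20, and the median after removing trends with GC content and length was 2.20. A response of the epithelial cells to the transgene is a hypothesis, untested apart from the genotype contrast, and the level of interferon itself was not tested. Reads shared among Schlafen, Ifit and histocompatibility paralogs remain open.

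The change from 10 to 55 weeks in wild-type mice was weighed second. Library group as the whole cause is argued against: genes called between first-group 10-week libraries and 3 of the 55-week libraries showed, between second-group 10-week libraries and the other 55-week libraries, at least 0.371 of their median change over 10 choices of libraries. That ratio is below 1, so a part from library group remains open, and library group called 0 genes within the 10-week mice by edgeR (1087 at an unadjusted p under 0.05). A lower share of epithelial cells would raise the markers of other cells alike. Stromal markers rose by 0.32 and mast, B and plasma cell markers by 1.62, which is 1.31 more. The rises were thus unequal, but the mast, B and plasma cell lists had been called in the same comparison, so this was not an independent test. A lower share as part of the change remains open, and a gain of mast, B and plasma cells with age is a hypothesis.

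The pancreatic-type enzyme genes that fell at 55 weeks, such as Clps and Pla2g1b, were weighed last. Pancreatic tissue in the wild-type scrapes is argued against, since Cpb1, the most abundant of 6 acinar genes examined (Prss2, Cpa1, Ctrb1, Cela2a, Pnlip and Cpb1, chosen after values were seen), stood at 0.00435% of Clps, and the trypsinogen gene Try10, itself among the genes that fell, averaged 13.9 CPM against 12035 CPM for Clps. The share of counts taken by a few genes shifts all genes alike, by 0.40 in the median at 55 weeks, which is a small part of the fall of Clps (−7.57, and −7.16 with library size as the only scaling). Loss of cells that express these genes with age in transgenic mice, or lower expression per cell, may each account for the fall, and bulk libraries leave them open.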

How the results depend on the processing

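The term for library group and the fits within 1 library group were tests chosen after the results were seen. Over all alternatives, list tests kept their direction and side of the threshold in 1691 instances, became stronger in 47, weaker in 76 and reversed in 1. The direction is that given by the list test, which can differ from the sign of the list median. Named genes did so in 9971, 81, 311 and 1. The reversed results were the endothelial markers at 10 weeks within the second library group (median −0.69, camera adjusted p = 0.00643) and Xbp1 at 55 weeks with library size alone (0.00024, edgeR adjusted p = 0.998), and the cause was not tested. The endothelial median itself did not change sign, at −0.085 in the main fit, where camera made no call. The planned sex term was not run, since all 28 libraries were male.

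Numbers of genes called changed as follows, and fewer libraries or a stricter threshold by construction lowers them. A 2-fold threshold gave 1066, 1789 and 4057 genes for genotype at 10, 25 and 55 weeks, 476 for wild-type mice from 10 to 55 weeks, 111 and 3389 for transgenic mice from 10 to 25 and 10 to 55 weeks, and 0, 2789 and 2219 for the changes of the genotype difference from 10 to 25 (1810 at an unadjusted p under 0.05), 10 to 55 and 25 to 55 weeks. The second library group alone gave 1891 for genotype at 10 weeks, 243 for wild-type mice from 10 to 55 weeks and 3636 for the change of the genotype difference from 10 to 55 weeks. The first alone gave 2803 for genotype at 10 weeks and 0 for the change from 10 to 25 weeks (1658 unadjusted). The library group term gave 0 (672 unadjusted), 626 and 208 for wild-type mice to 25 and to 55 weeks and transgenic mice to 25 weeks, and the cause was not tested.

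For wild-type mice from 10 to 25 weeks library size alone, only the groups compared, 10-week replicates 4 and 5 left out, and limma-voom each gave 1. For transgenic mice from 10 to 25 weeks library size alone gave 914, no filter 246, 10-week replicates 4 and 5 left out 123, DESeq2 1132 and limma-voom 2972. For the change of the genotype difference from 10 to 25 weeks library size alone (2350 unadjusted) and the replicate block (1373 unadjusted) gave 0, DESeq2 47 and limma-voom 130. The replicate block gave 4473, 5335 and 8800 for genotype at 10, 25 and 55 weeks, though replicate numbers do not pair the mice.

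Ppard stayed higher in every alternative run but missed the threshold at 25 weeks with only the groups compared (0.25, adjusted p = 0.126) and within the first library group (0.36, adjusted p = 0.0538), and at 55 weeks with the replicate block (0.23, adjusted p = 0.0604). Without a filter the correlations between ages were 0.354, 0.285 and 0.354, with more genes of few counts by construction.

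Leaving out each library gave 4334 to 5476, 4863 to 6807 and 8819 to 9245 genes for genotype at 10, 25 and 55 weeks, 0 to 2 and 1203 to 1972 for wild-type mice to 25 and 55 weeks, 64 to 1862 and 7572 to 8031 for transgenic mice, and 0 to 32, 5328 to 5787 and 3944 to 5148 for the changes of the genotype difference from 10 to 25, 10 to 55 and 25 to 55 weeks. Wild-type replicates 1, 2 and 3 of 10 weeks and 1 and 4 of 25 weeks each took the wild-type count to 25 weeks to 0. Ppard ranged from 0.51 to 0.61, 0.23 to 0.37 and 0.185 to 0.261 at the 3 ages.

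Besides the estimated correlation, list calls were lost with library size alone for mucous neck and SPEM markers at 10 weeks (adjusted p = 0.0604), cytokine genes at 10 and 25 weeks, immune checkpoint genes at 25 weeks (0.0902) and intestinal markers at 55 weeks (0.382). They were lost within the first library group for mucous neck and SPEM markers at 10 weeks (0.140), within the second for matrix remodelling genes at 10 weeks (0.410), without a filter for PPAR targets at 55 weeks, and with only the groups compared for adipocyte markers at 55 weeks (0.0583).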

Other observations

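No test in this part was chosen after the results were seen.

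Several genes moved apart from their lists or between ages. Il33 was higher at 10 weeks (2.12) and 25 weeks (2.37), and did not pass the test at 55 weeks (−0.23). Noxo1 went from 0.34 and 0.52 to 3.81 at 55 weeks. Duox2 was higher at every age (3.19, 2.42 and 3.63), as was Vnn1 (3.68, 4.61 and 5.77). Gsdmc4 was 0.43 and 0.66 at 10 and 25 weeks and −1.94 at 55 weeks.

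The lists without a camera call at 10 or 25 weeks, in order of age, were as follows. Hypoxia and glycolysis genes had 6, 4 and 7 of 22 higher and 5, 6 and 6 lower. Stem and progenitor genes had 3, 2 and 7 of 16 higher (2 at 10 weeks adjusted over the list alone) and 2, 3 and 5 lower. Unfolded protein response genes had 5, 6 and 4 of 23 higher (3 at 55 weeks adjusted over the list alone) and 0, 1 and 3 lower. Lipid and sterol synthesis genes had 5 and 4 of 19 higher and 2 and 1 lower at 10 and 25 weeks. Mast cell markers had 1, 0 and 2 of 10 higher and 1, 3 and 7 lower (2 at 25 weeks adjusted over the list alone). Fibroblast markers had 2, 3 and 2 of 16 higher and 0, 0 and 4 lower, and smooth muscle markers 0 of 13 higher and 0, 1 and 6 lower (0 at 25 weeks adjusted over the list alone). Endothelial markers had 2, 1 and 3 of 13 higher (2 at 25 weeks adjusted over the list alone) and 0, 4 and 4 lower. Neuron and glia markers had 0, 0 and 1 of 4 higher and 2, 0 and 3 lower (3 at 10 weeks adjusted over the list alone). Squamous epithelium markers had 1, 2 and 5 of 17 higher and 2, 0 and 7 lower (0 at 10 weeks and 8 at 55 weeks adjusted over the list alone). Intestinal epithelium markers had 4 and 7 of 21 higher and 2 and 3 lower at 10 and 25 weeks, and Wnt target genes 1 and 2 of 14 higher and 1 and 1 lower. At 25 weeks PPAR target and fatty acid oxidation genes had 6 of 30 higher and 9 lower (8 and 10 adjusted over the list alone), myeloid markers 3 of 22 higher (2 adjusted over the list alone), B and plasma cell markers 2 of 12 lower (1 adjusted over the list alone), and T and natural killer cell markers 0 of 10 past the test.

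Adipocyte markers had 3, 3 and 0 of 5 higher and 2, 2 and 3 lower, and pancreatic acinar markers 1, 0 and 1 of 7 higher and 3, 4 and 5 lower. Both lists were called lower by camera at 55 weeks (camera adjusted p = 0.0396 and 0.0225, adjusted p = 0.262 and 0.160 with an estimated correlation). Erythroid markers had 2 of 4 lower at 10 weeks (4 adjusted over the list alone) and 4 of 4 at 55 weeks (camera adjusted p = 0.00596, adjusted p = 0.262 with an estimated correlation). Immediate early and heat shock genes had 6, 7 and 7 of 20 higher (9, 8 and 4 adjusted over the list alone) and 0 lower, with a call at 25 weeks (camera adjusted p = 0.0191, adjusted p = 0.676 with an estimated correlation). Claudins and tight junction genes had 6 of 15 higher (7 adjusted over the list alone) and 2 lower at 10 weeks (camera adjusted p = 0.0953).

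The median and the mean of a list differed in sign for the unfolded protein response, PPAR target, B and plasma cell, smooth muscle and endothelial lists at 10 weeks, for the PPAR target, pit cell, T and natural killer cell and squamous lists at 25 weeks, and for the stem and progenitor, fibroblast, endothelial and squamous lists at 55 weeks.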
